A study of Homo sapiens with 10 samples.

How the data were processed

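DNase-seq had been performed on A549 cells, an established human lung adenocarcinoma line, with and without correction of its SMARCA4 mutation. Per the labels, DNA was enriched by polyethylene glycol precipitation with size selection, and libraries were made by a low-input single-stranded protocol. Per the submitters' processing notes, BWA 0.7.12 and SAMtools 1.2 were used with builds GRCh38 and hg38. The hotspot caller and the read totals are not given in the sources used here. The authors called hotspots separately in each library, at a false discovery rate of 0.05 per the deposited lists' names, so each library has a list of its own.

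Each deposited list gave a hotspot's chromosome, start and end, a score, and a −log10 value. The authors' −log10 column ran from 1.3 to a cap of 100, and the deposited score was 10 times that value, rounded (largest difference 0.5). The other deposited columns, a strand field and placeholders of -1, held no measurement. The score and −log10 values are the authors' own and were used only to rank hotspots within a library. Coordinates are those of GRCh38 and are printed counted from 1. Hotspots on chromosomes 1 to 22 and X were used, and those on chromosome Y and unplaced contigs were set aside (between 126 and 582 per library). Longer lists can come from deeper sequencing as well as from more open chromatin, and a calling threshold turns small differences in signal into presence or absence.

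Libraries were grouped by the genotype in their labels, 6 rescue and 4 null, and numbered within a group by order only. The number of hotspots, the bases covered, the share near gene ends and the Jaccard index were compared by exact permutation over all 210 splits of the libraries into 6 and 4, with Benjamini-Hochberg adjustment over these 4 measures. Hotspots of all libraries were merged where they overlapped or touched into 186717 regions, and a library had a region if its hotspots covered at least 1 bp of it. Gained regions were present in 6 of 6 rescue and 0 of 4 null libraries, and lost regions in 0 of 6 and 4 of 4. Fisher's exact test was applied per region and to gene-end shares, against regions present in 2 to 8 libraries as background.

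Gene positions came from the RefSeq gene table of GRCh38.p14, with 19974 protein-coding genes on these chromosomes. It holds gene spans without strand or exons, so the planned promoter (within 1 kb of the 5′ end) became a window of 1000 bp around either end of a protein-coding gene. A territory likewise held the bases nearer to an end of that gene than to any end of another protein-coding gene, at most 50000 bp to each side. A gene near a region is its neighbour and not a known target. The planned motif search was not run because no genome sequence was used here.

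Covered bases per territory were scaled to the mean library total, 500 was added and log2 taken, territories with a mean of at least 500 covered bases were kept (15139), and groups were compared with limma 3.58.1 (moderated test with an intensity trend, Benjamini-Hochberg adjusted p of 0.05). Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 19 lists. Those lists held 516 genes, of which 512 matched the reference. They were SWI/SNF subunits, lung epithelial identity, epithelial junctions and keratins, mesenchymal and extracellular matrix, AP-1 factors, YAP/TEAD targets, NRF2 targets, glucocorticoid receptor targets, interferon and antigen presentation, NF-kB and inflammatory cytokines, hepatic and gastrointestinal, neuronal and neuroendocrine, HOX, cell cycle and growth control, WNT and TGF-beta, housekeeping, blood cell, fibroblast and endothelial markers. COL1A1 and COL3A1 are in both the mesenchymal and the fibroblast list.

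Named genes followed a rule fixed before the data were examined, as were the tests, lists and most alternatives. SMARCA4 and SMARCA2 were named always. The 10 largest rises and 10 largest falls were taken among genes past the threshold whose groups did not overlap, with up to 4 members of each list past the threshold by smallest p; a gene that this rule names is not reported here. Regions named were the 5 gained and 5 lost with the most covered bases, and genes with the most gained regions were chosen after their values were seen. Alternatives were equal-length lists, hotspots of at least 200 bp, 50% overlap, 200 bp bins, merging across 150 bp, 1 exception allowed, adjustment over all regions, identifier series, other pseudocounts (100 and 2000), no filter, other scalings, territories of 10000 bp, a gene-end window of 2500 bp and each library left out in turn.

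Territory calls were checked on simulated data for this comparison with 15139 territories, in which 44 of 100 planted log2 changes of 0.5 and 83 of 100 of size 1 were recovered, with 12 false calls. The simulated territories varied independently and library totals did not differ between groups. Those false calls therefore do not cover errors from scaling or from variation shared between territories. Region calls were tested on simulated data with 186717 regions drawn at the libraries' own list lengths. All 200 planted gained regions were recovered, and 137 unchanged regions were called gained and 17 lost. The call requires complete presence and absence, so a single missed hotspot would hide a gained region. Recovery of all 200 says little about how often such misses occur in the real lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.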

Results

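Accessible chromatin was compared in A549 cells, a human lung adenocarcinoma line that lacks functional SMARCA4, and in A549 cells in which that mutation had been corrected. SMARCA4 (BRG1) is an ATPase of the SWI/SNF chromatin remodelling complexes. DNase-seq, which reads out where the nuclease DNase I cuts open chromatin, was represented by 1 list of hotspots (regions of enriched cutting) per library. There were 6 libraries of the corrected genotype, called rescue here, and 4 of the parental genotype, called null. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Hotspots on chromosomes 1 to 22 and X numbered 113222, 115271, 112145, 83670, 95894 and 132806 in rescue 1 to 6, and 84157, 72284, 89589 and 73217 in null 1 to 4. The lists give no read totals, so the sequencing depth is unknown.

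The first question was whether the extent and placement of accessible chromatin differed with SMARCA4. Rescue libraries held more hotspots than null libraries, and a smaller share of them lay beside genes. The number of hotspots was 108835 ± 17012 (SD, n = 6) in rescue and 79812 ± 8458 (SD, n = 4) in null, a ratio of 1.36 (exact permutation test, two-sided p = 0.0286, Benjamini-Hochberg adjusted p = 0.0381 over 4 library measures). The share of hotspots within 1 kb of either end of a protein-coding gene was 16.2% ± 1.8 (SD, n = 6) in rescue and 21.2% ± 1.2 (SD, n = 4) in null (exact permutation test, two-sided p = 0.00952, adjusted p = 0.019). Each of the 6 rescue libraries had a lower share than each of the 4 null libraries, and this p is the smallest that the 210 splits of 10 libraries can give. Within each genotype, however, the share was lowest in the longest list and highest in the shortest. Rescue 4 and null 1, with lists of similar length (83670 and 84157 hotspots), had shares of 19.1% and 20.6%. The lower share in rescue may therefore follow list length in part, and this was not tested. The bases covered by hotspots, 44.3 Mb ± 8.4 (SD, n = 6) in rescue and 35.7 Mb ± 5.8 (SD, n = 4) in null, did not differ by more than the spread (exact permutation test, two-sided p = 0.105). Without rescue 4 or without null 3 that difference passed (exact permutation test, smallest p = 0.0476). Leaving out null 2 or null 4 raised the p of the hotspot count to 0.0714, and permuting only within the 2 series of library identifiers in the sample titles raised it to 0.167 and that of the gene-end share to 0.0833. The 24 splits within series allow no smaller two-sided p, so neither call holds within them. The first series held 5 rescue and 1 null library and the second 1 rescue and 3 null libraries.

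**Figure D1:**
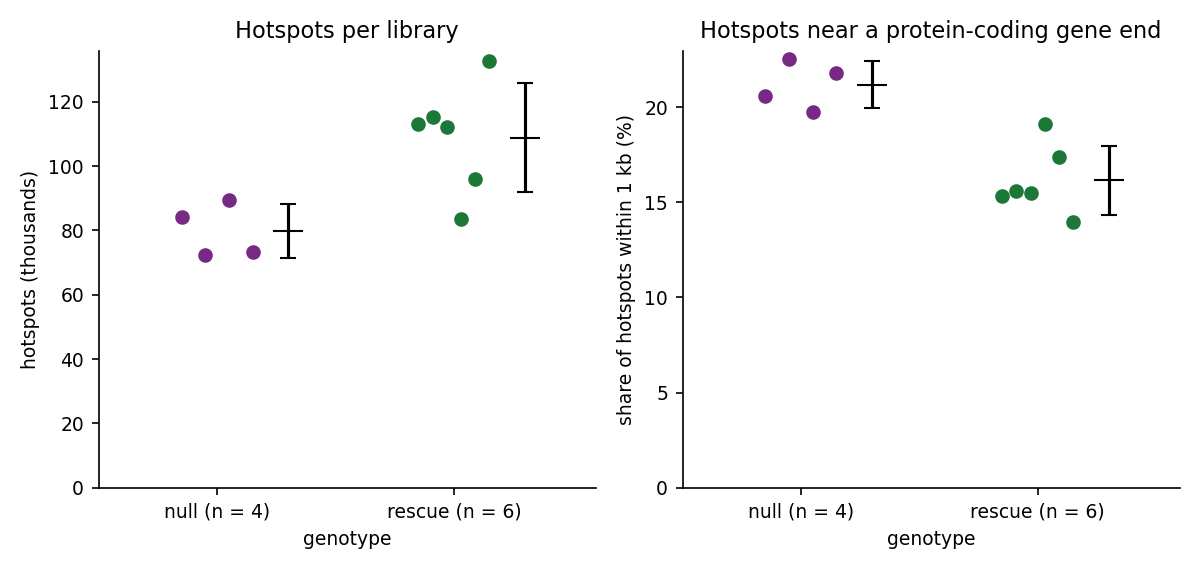
Hotspots per library (left, axis in units of 1000) and the percentage of hotspots within 1 kb of either end of a protein-coding gene (right), by genotype. Points are libraries and bars are the mean ± SD. All 6 rescue libraries lie below all 4 null libraries in the right panel (16.2% ± 1.8 against 21.2% ± 1.2).

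Hotspot sets grouped by genotype. The base-pair Jaccard index, the bases shared by a pair of libraries over the bases in either, averaged 0.642 over the 21 pairs of the same genotype and 0.527 over the 24 pairs of different genotypes. The difference of 0.115 was the largest of all 210 labelings of the libraries (exact permutation test, one-sided p = 0.00476, adjusted p = 0.019), and of the 24 labelings within the identifier series (one-sided p = 0.0417). No pair was close to identical: the highest index was 0.71, between null 1 and null 3.

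**Figure D2:**
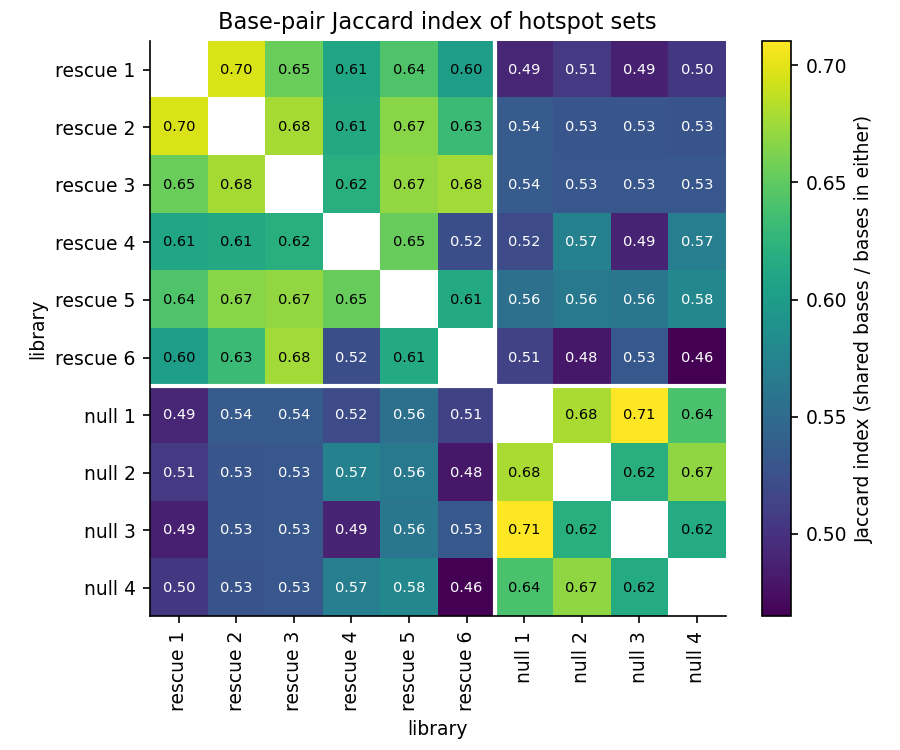
Base-pair Jaccard index of each pair of libraries, with rescue and null libraries separated by white lines. Pairs of the same genotype averaged 0.642 and pairs of different genotypes 0.527.

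The second question was which regions opened or closed. Regions detected in all 6 rescue libraries and in no null library, called gained, numbered 7491, while regions detected in all 4 null libraries and in no rescue library, called lost, numbered 373. Gained regions lay farther from gene ends than lost regions, while 49.7% of gained, 53.9% of lost and 50.3% of other variable regions lay inside gene spans. The gained region with the most covered bases was at chromosome 3, 139308289 to 139311159, outside any protein-coding gene span, with 1910 ± 605 covered bases (SD, n = 6). Among lost regions the largest lay at chromosome 20, 44355147 to 44356588, across an end of HNF4A, a liver and gut nuclear receptor, with 941 ± 447 covered bases (SD, n = 4).

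The next gained regions by covered bases were at chromosome 17, 48482973 to 48484638, at 38744 bp from the nearest gene end, that of SKAP1, and at chromosome 15, 89067282 to 89068842, inside the span of ABHD2. A gained region at chromosome 7, 46908590 to 46910341, lay 365688 bp from the nearest gene end, that of TNS3, and another at chromosome 8, 98398499 to 98400063, lay inside STK3, a Hippo pathway kinase. These 4 regions averaged 1486 ± 151, 1418 ± 173, 1343 ± 487 and 1307 ± 270 covered bases in rescue (SD, n = 6). Lost regions included chromosome 17, 39702819 to 39703975, inside ERBB2, a receptor tyrosine kinase, with 862 ± 446 covered bases (SD, n = 4). Another, at chromosome 1, 217348712 to 217349736, lay 77768 bp from GPATCH2 and had 931.3 ± 67.3 covered bases (SD, n = 4). The remaining pair were at chromosome 8, 9095698 to 9096690, inside ERI1, and at chromosome 2, 42999395 to 43000403, with 856 ± 125 and 845 ± 114 covered bases (SD, n = 4). Spans and nearest ends are those of protein-coding genes only. The annotation used gives gene spans but no exons or strand, so exonic and intronic positions were not told apart.

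Several genes had clusters of gained regions around them. The territory of NREP, the stretch nearer to an end of that gene than to any other gene and within 50 kb, held 8 gained regions and no lost region. Territories of ADAM19, CRADD, FLI1, HS3ST3A1, PLPP4 and TRABD2B held 5 each. FLI1, an ETS transcription factor of blood and endothelial cells, lies at chromosome 11, 128685132 to 128813267. The gained regions drawn around it lay between 128669558 and 128757619. The last of these is farther than 50 kb from either end of FLI1, so they are not the same 5 as in its territory.

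Gene-end shares were 2.48% (95% Wilson interval 2.15 to 2.86) of gained regions, 8.85% (6.37 to 12.2) of lost regions and 6.08% (5.90 to 6.25) of the 72149 other regions found in 2 to 8 libraries. These intervals cover counting error only, and regions are not independent replicates. Gained regions were less often at gene ends than lost regions (odds ratio 0.262, Fisher's exact test, two-sided p = 2.5e-09) and than the other variable regions (odds ratio 0.394, p = 4.6e-45). Lost regions exceeded the other variable regions (odds ratio 1.5, Fisher's exact test, p = 0.0298), a call that ended when rescue 1, rescue 2 or rescue 5 was left out, with p up to 0.0779. It also ended with hotspots of at least 200 bp and with a gene-end window of 2500 bp. Median distances to a gene end were 44374 bp for gained, 27412 bp for lost, 34555 bp for the other variable regions and 11589 bp for the 41946 regions found in all 10 libraries, of which 28.0% lay at a gene end. Chromosome 19 held 60 gained and 32 lost regions, which made its gained share of variable regions 0.316 times and its lost share 3.38 times that of the genome.

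Each gained or lost region had a two-sided Fisher's exact p of 0.00476, and 0.0141 after Benjamini-Hochberg adjustment over the 23301 regions found in exactly 4 or 6 libraries. This adjustment pools both directions, so the more numerous gained regions lower the value of the lost ones. Of regions in exactly 6 libraries 60.9% were gained, while of those in exactly 4 libraries 3.39% were lost. Other divisions of the libraries into 6 and 4 averaged 0.36% of the gained and 19.7% of the lost count. Adjusted over all 186717 regions, Fisher's exact test called 0 regions, with 16199 in the gained and 1879 in the lost direction at an unadjusted p under 0.05. With lists cut to 72284 hotspots each, gained regions numbered 3877 and lost regions 1516, and without null 2 or null 4 the lost regions numbered 855 and 858. Leaving out a library relaxes the rule, so a rise of that kind is built in.

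**Figure D3:**
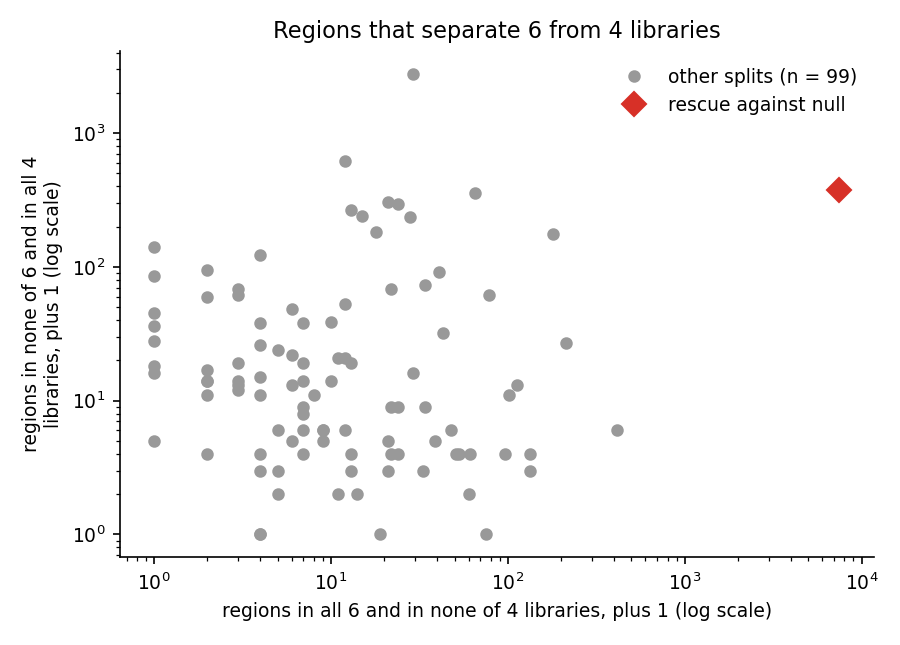
Regions found in all 6 and in none of 4 libraries (horizontal) against regions found in none of 6 and in all 4 (vertical), plus 1 and on log axes, for 100 divisions of the libraries into 6 and 4. Rescue against null (red diamond) gave 7491 and 373, while the highest of the other 99 (grey) was 411 on the horizontal axis and 2773 on the vertical.

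The third question was which genes lay near the altered chromatin. Covered bases rose most around PLPP4, CLVS1 and TDO2 and fell most around CACNA1D, HUNK and SEMA4G. PLPP4, a phospholipid phosphatase gene on chromosome 10, rose by a log2 difference of 2.82 ± 0.40 (SE), from 373 ± 275 (SD, n = 4) to 6594 ± 4285 bp (SD, n = 6; limma, adjusted p = 0.000564). TDO2, which encodes tryptophan dioxygenase on chromosome 4, rose by 2.35 ± 0.12 (SE; limma, adjusted p = 5.0e-07). CACNA1D, a voltage-gated calcium channel gene on chromosome 3, fell by 2.05 ± 0.37 (SE) on the log2 scale, from 3108 ± 1280 (SD, n = 4) to 422 ± 510 bp (SD, n = 6; limma, adjusted p = 0.0026). All differences are on the scale of log2(covered bases + 500), which understates the change of low territories.

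Other large rises were at CLVS1 (2.40), TLR4, the lipopolysaccharide receptor (2.21), BABAM2 (2.14), FLI1 (2.14), ADAMTS12 (2.10), the growth factor gene FGF5 (2.10) and SLC39A12 (2.04). OR56B1 averaged 1625 ± 469 bp (SD, n = 6) in rescue and was at 0 bp in each null library. Large falls included HUNK (-1.88), SEMA4G (-1.69), DEFA6 (-1.58), the small MAF factor MAFK (-1.56), RAB26 (-1.55), the amino acid transporter SLC7A5 (-1.51), the sodium channel subunit SCNN1B (-1.48), AKR1C8 (-1.44) and ERFL (-1.38). Each of these 10 rises and 10 falls, PLPP4, TDO2 and CACNA1D included, passed with limma, and its 6 rescue libraries lay wholly above or below its 4 null libraries. Falls at RAB26, SLC7A5 and AKR1C8 no longer passed with limma without scaling (adjusted p = 0.0735, 0.0543 and 0.0678), though each kept its direction.

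SMARCA4 itself, on chromosome 19 from 10961030 to 11062273, did not pass (log2 difference -0.24 ± 0.11, SE; limma, adjusted p = 0.106), nor did its paralogue SMARCA2 (-0.13 ± 0.10, SE; adjusted p = 0.335). Without scaling these differences changed sign, to 0.01 and 0.15. Hotspots do not show the corrected mutation and cannot check the genotype labels. Of 15139 territories tested, 1192 had more and 2806 had fewer covered bases in rescue at an adjusted p of 0.05, and 795 and 1729 of them separated the groups completely. Chance gives such separation, in either direction, for 0.952% of all territories, but passing limma's threshold already favours it. Higher calls dropped with territories of at most 10 kb per side, and calls in both directions dropped with the identifier series as a covariate, with counts given further below. The balance of calls followed the scaling: 29.8% were higher after scaling to each library's total, with a median over all territories of -0.16, against 1418 higher and 121 lower without scaling, 92.1% higher (median 0.06). Quantile normalization gave 1606 higher and 1098 lower, 59.4% higher (median -0.06), and scaling to the total inside the territories 1562 and 1138, 57.9% higher (median -0.07). A call of fewer covered bases is therefore relative to the scaling, and leaving out null 1 or null 2 left 1549 or 1722 such calls. Of the 92 named genes, 42 no longer passed without scaling, all of them falls except CCN2. With the identifier series as a covariate 17 of the 92 no longer passed, among them RAB26, SMARCC2, CLDN1, ITGAM, CORO1A and CCN2 (adjusted p from 0.0524 for RAB26 to 0.142 for CORO1A).

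Gene lists fixed before the data were examined were then compared with all other territories. Territories of mesenchymal and matrix genes, fibroblast markers and endothelial markers were higher in rescue. Interferon and antigen presentation genes were higher and housekeeping genes lower only with the preset correlation (camera, adjusted p = 0.0753 and 0.291 with an estimated correlation). Of 32 mesenchymal and extracellular matrix genes measured, 13 rose and none fell (camera, adjusted p = 8.0e-08; adjusted p = 0.0138 with an estimated correlation). CD44, the hyaluronan receptor, rose by 0.79 ± 0.10 (SE), MMP2, a gelatinase, by 1.21 ± 0.22 (SE), SPARC by 0.61 ± 0.11 (SE) and the collagen gene COL1A1 by 0.66 ± 0.13 (SE). Territories of at most 10 kb per side left CD44 at 0.05 and COL1A1 at 0.30, neither past the threshold.

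Endothelial markers rose at 5 of 12 genes and fell at none (camera, adjusted p = 1.6e-05; adjusted p = 0.0138 with an estimated correlation). They included ERG (0.80 ± 0.11, SE), the angiopoietin receptor gene TEK (1.05 ± 0.15, SE), PECAM1 (0.61 ± 0.12, SE) and ROBO4 (0.91 ± 0.18, SE). Fibroblast markers rose at 7 of 16 genes and fell at 1 (camera, adjusted p = 3.1e-04; adjusted p = 0.0153 with an estimated correlation). DPT rose by 0.87 ± 0.15 (SE) and COL3A1 by 0.75 ± 0.15 (SE), and TCF21, a mesenchymal transcription factor, fell by 0.64 ± 0.10 (SE) on the log2 scale. With territories of at most 10 kb per side the fibroblast list gave an adjusted p of 0.0511. Blood cell markers, also a list for another cell type, rose at 2 and fell at 2 of 11 genes (camera, adjusted p = 0.372). PTPRC (CD45) rose by 1.67 ± 0.16 (SE) and CSF1R by 1.91 ± 0.22 (SE), while ITGAM (-0.52) and CORO1A (-0.48) fell, the latter not without null 4 (-0.28, adjusted p = 0.123).

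Interferon and antigen presentation genes rose at 8 and fell at 2 of 31 (camera, adjusted p = 0.0228; adjusted p = 0.0753 with an estimated correlation), and without null 1 the adjusted p was 0.0635. CIITA, the transactivator of class II antigen presentation genes, rose by 1.52 ± 0.15 (SE), IFI44 by 1.05 ± 0.23 (SE) and IFI44L by 0.88 ± 0.13 (SE), and IRF7 fell by 0.43 ± 0.10 (SE) on the log2 scale. The list's median, -0.06, was below 0 but 0.10 above the median of all territories. Housekeeping genes rose at 0 and fell at 11 of 27 with limma (camera, adjusted p = 0.00695; adjusted p = 0.291 with an estimated correlation). POLR2A, the large subunit of RNA polymerase II, fell by 0.57 ± 0.11 (SE) and the ribosomal protein gene RPL13A by 0.94 ± 0.20 (SE) on the log2 scale. Without scaling 1 housekeeping gene fell.

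**Figure D4:**
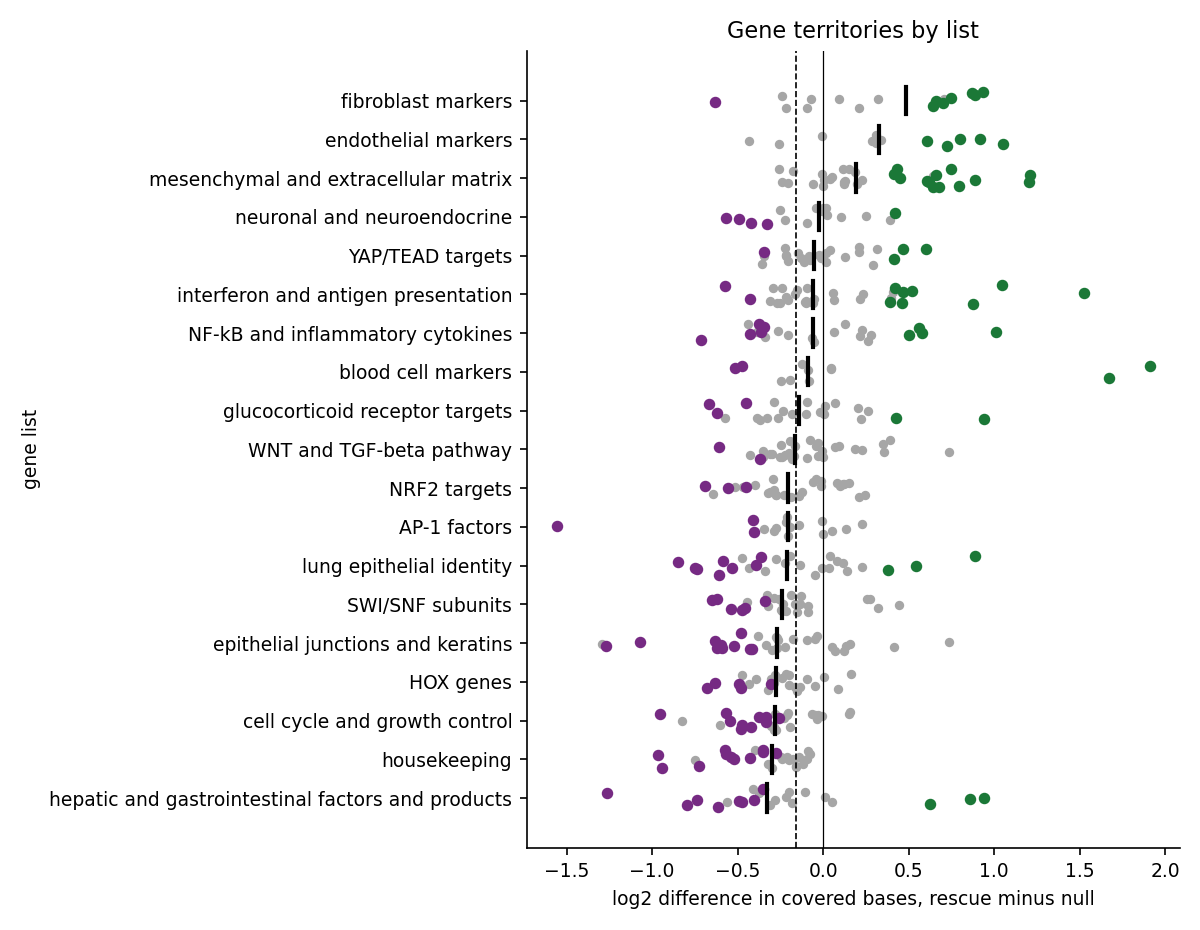
Log2 difference in covered bases (rescue minus null) of the measured members of each of the 19 gene lists. Points are genes, green or purple where limma's adjusted p is under 0.05 and grey otherwise; thick bars are list medians and the dashed line is the median of all territories (-0.16). Fibroblast, endothelial and mesenchymal medians stand at 0.48, 0.32 and 0.19.

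Among epithelial genes that passed, falls outnumbered rises, as they did over all territories (2806 lower and 1192 higher). The tests of the epithelial lists did not pass. Without scaling no junction gene passed with limma and lung identity genes rose at 4 and fell at 1. Epithelial junction and keratin genes fell at 10 of 30 and rose at none (camera, adjusted p = 0.218), among them the tight junction gene TJP3 (-1.07 ± 0.19, SE), JUP, which encodes plakoglobin (-0.60 ± 0.12, SE), CLDN1 (-0.52) and CLDN7 (-0.62). Lung epithelial identity genes rose at 3 and fell at 8 of 26 (camera, adjusted p = 0.776). The airway mucin gene MUC5B (-0.75), ELF3 (-0.85) and the lung transcription factor gene NKX2-1 (-0.61) fell and HOPX (0.89) rose. Hepatic and gastrointestinal genes rose at 3 and fell at 8 of 22 (camera, adjusted p = 0.235, and 0.021 without scaling), with falls at ONECUT1 (-0.80) and FGG (-0.61) and a rise at the bile acid receptor gene NR1H4 (0.86). Cell cycle and growth genes fell at 10 of 28 (camera, adjusted p = 0.0518, passing in 8 of 21 alternatives with 0.0135 the lowest, without null 4, and 0.36 with an estimated correlation), ERBB2 by 0.95 ± 0.13 (SE) and ERBB3 by 0.47 ± 0.11 (SE) on the log2 scale. Without scaling the falls of CLDN1, CLDN7, ELF3, NKX2-1, FGG, ERBB3, TJP3 and JUP no longer passed with limma, with adjusted p from 0.0615 for TJP3 to 0.437 for CLDN1. Each of them kept its direction.

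No other list passed. Over all territories tested 18.5% passed as lower and 7.87% as higher, which is the background for the counts that follow. YAP/TEAD target genes rose at 3 and fell at 1 of 26 (camera, adjusted p = 0.103), with RBMS3 at 0.60 and NT5E at 0.47, and the list passed without null 3 (adjusted p = 0.0314) and with the identifier series as a covariate (0.0286). SWI/SNF subunit genes fell at 6 of 27 (0.217), with SMARCD3 at -0.65 and SMARCC2 at -0.46, HOX genes at 5 of 25 (0.217), with HOXC4 at -0.63 and HOXB3 at -0.68, AP-1 factors at 3 of 16 (0.581) and NRF2 targets at 3 of 28 (0.773), with GPX2 at -0.69; these values in parentheses are camera's adjusted p. Glucocorticoid receptor targets rose at 2 and fell at 3 of 22 (camera, adjusted p = 0.751): the receptor gene NR3C1 (0.94) and SGK1 (0.43) rose, and LCN2 (-0.62) and CEBPD (-0.66) fell. NF-kB and cytokine genes rose at 4 and fell at 5 of 22 (camera, adjusted p = 0.372), with IL6 at 1.01, CSF2 at 0.56, TNFAIP3 at 0.50 and NFKB1 at -0.43. With territories of at most 10 kb per side NR3C1, SGK1 and TNFAIP3 turned negative (-0.03, -0.20 and -0.39). Neuronal and neuroendocrine genes rose at 1 and fell at 4 of 16 (camera, adjusted p = 0.76), and WNT and TGF-beta genes fell at 2 of 31 (camera, adjusted p = 0.814).

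Adjusted over the list alone, the counts of higher and lower genes were 13 and 0 for the mesenchymal list, 8 and 1 for the endothelial, 8 and 1 for the fibroblast, 8 and 2 for the interferon and 0 and 11 for the housekeeping list. They were 2 and 12 for epithelial junctions, 3 and 9 for lung identity, 3 and 11 for hepatic genes and 0 and 12 for the cell cycle list.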

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

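Tests of chance for the region counts and the gap between them, of the equal-length ratio with a library left out, of identifier series, of the spread of gained regions over 3 chromosomes and of cells of another type were chosen only after the result was seen. Hotspots on chromosome Y lay outside the comparisons and were more frequent in rescue, 232 ± 57.2 (SD, n = 6), than in null, 57.8 ± 53.8 (SD, n = 4; exact permutation test, two-sided p = 0.00952, adjusted p = 0.0667 over 7 further library measures). Null 1 held 3 and null 3 held 21, against 95 in null 2 and 112 in null 4. Rescue 6 had 250 hotspots on unplaced contigs, far above the next rescue library at 129.

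Single libraries stood far from the rest of their group at 10 territories, values being scaled covered bases. Null 2 was low at CACNA1D (1220 bp, next 3413), null 1 at HUNK (3626, next 3883), null 4 at NR3C1 (847, next 1171), rescue 6 at MUC5B (1680, next 2224) and rescue 6 at ONECUT1 (802, next 1208). Null 4 was high at ROBO4 (927, next 294), null 3 at SMARCD3 (1470, next 1306) and at SLC39A12 (122, next 0), null 2 at TDO2 (136, next 0) and rescue 1 at IL6 (4024, next 3194). Among 204 groups examined chance alone gives about 10.2 such libraries, and 11 were found.

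For the first pattern, chance is argued against for the gained regions. Only 1 of 100 divisions of the libraries, the real one, gave as many (7491, highest other 411), and the others averaged 0.36% of that count. The case is weaker for the lost regions: 3 divisions, the real one included, gave as many (373, highest other 2773, which sets the longest lists, rescue 1, 2, 3 and 6, apart). The other divisions averaged 19.7% of the lost count. For the excess, 1 division, the real one, gave as large a gap between the counts (7118, highest other 2745). The ratio of the counts decides nothing about chance, since it rests on small counts in other divisions (411 and 5 in 1 of them). Longer rescue lists are argued against for the gained regions themselves. Of 11329 regions gained among the other 8 libraries rescue 4 (83670 hotspots) held 74.1% and null 3 (89589 hotspots) 11.7%, a gap of 62.5 percentage points. For the excess they are argued against as the whole source, since equal-length lists left a ratio of 2.56, above the bound of 1.5 set beforehand. Leaving out each library gave ratios of 1.72 to 2.57 (lowest without null 4, with 2729 lost regions, and null 2, 1.88 with 2451). Fewer libraries relax the rule for both classes, so these ratios add no test of list length. With all hotspots gained regions outnumbered lost ones by a ratio of 20.1, so list length may account for part of it. Identifier series are argued against for the counts, as 1 of the 24 divisions that keep the series, the real one, gave as many gained (highest other 132) and as many lost regions (highest other 237), and for the similarity of libraries as the only source, as again 1 of 24 gave as large a difference of the mean Jaccard index within and between groups (0.115, highest other 0.0498). Null 1 averaged 0.676 with null libraries of the other series and 0.527 with rescue libraries of its own, and rescue 6 averaged 0.61 with rescue libraries of the other series and 0.493 with null libraries of its own, though it overlapped rescue 4 (0.524) less than null 3 (0.533). Extra copies of 3 chromosomes are argued against as the source of most gained regions. The 3 with the most gained regions, chromosomes 1, 2 and 3, held 24.4% of them, so no other 3 held more. They also held the most variable regions (7313, 6459 and 5477), so even this share need not come from extra copies. The bound set beforehand for copy number was 0.5 to 2 times the genome-wide share. It held at the top (1.23) and not for chromosome 19 (0.316), so other copy-number differences stay open. Sublines of A549 may also differ, as the chromosome Y counts vary within null, and were not tested apart from the genotype.

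The second pattern is the fall of housekeeping territories. Territory calls exceed chance, with 1 of 100 divisions giving as many calls, the real one, in each direction (1192 higher, highest other 437; 2806 lower, highest other 179). Both of those other counts came from the division that sets the longest lists, rescue 1, 2, 3 and 6, apart. List length may therefore add to the territory calls, and this was not tested. Scaling stays open for the fall, since without it the housekeeping median was -0.104 (95% bootstrap interval -0.195 to 0.0454). The list's place below all territories, a log2 difference of -0.137 scaled and -0.167 unscaled, hardly depends on a factor common to all territories of a library, so it decides nothing about scaling. Wider calls around constitutive regions in null stay open as well, with 668 bp in rescue and 672 bp in null covered per region found in all 10 libraries, a difference of -4.42 bp within the spread of the libraries. Medians of the same regions went the other way, 517 bp in rescue and 491 bp in null (exact permutation test, two-sided p = 0.514), while the 90th percentile of hotspot width, 822.5 bp in rescue and 981.25 bp in null, went with wider calls (p = 0.0286, adjusted p = 0.1 over 7 further library measures). The genotype is untested beside these.

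For the third pattern, the rise of fibroblast and endothelial markers, cells of another type in the rescue cultures stay open: 43.8% of the fibroblast and 41.7% of the endothelial genes measured passed as higher. A bound of 50%, first written with that value already known, would have argued against such cells. It was replaced by a bound of 10% because a partial admixture could also give 41.7%, so this test decides nothing. PDGFRA (-0.22), PDGFRB (0.09) and CDH5 (-0.01) did not pass, TCF21 fell (-0.64), and the blood list did not pass. Labels give an established cell line with no sort or gate, and a changed state of the rescue cells themselves may equally account for the rise.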

How the results depend on the processing

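The leave-two-out runs, scaling to the total inside territories, and identifier series as strata for covered bases, the gene-end share and library similarity were added after the data were seen. No paired analysis was possible because replicate numbers only name the libraries. The motif search was not run, and equal-length lists fix the hotspot count by construction. Read depth is unknown, so hotspots near the calling threshold limit every count. Causes were not tested unless given.

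Gained and lost regions numbered 3877 and 1516 with equal-length lists, 13329 and 961 in 200 bp bins, where a region spans several bins, 17833 and 2854 with 1 exception allowed, and 0 and 0 when Fisher's test was adjusted over all regions or stratified by identifier series, where 24 splits allow no two-sided p under 0.0833. Lost regions numbered 1173 without rescue 6 and null 2. Leaving out each library gave 7610 to 10009 gained and 395 to 858 lost regions. Fewer libraries relax the rule for both classes, so these rises, that to 1173 included, are built in and test no robustness. Within identifier series the exact permutation p was 0.167 for the hotspot difference of 29023 and for covered bases, 0.0833 for the gene-end share difference of -5.0155 percentage points, which no longer passed, and 0.0417 (one-sided) for library similarity. The hotspot difference ranged from 24229 to 34056 with a library left out; covered bases differed by 5876795 to 11055114, past the threshold without rescue 4 or null 3 (exact permutation test, smallest p = 0.0476). The odds ratio of lost regions at gene ends was 1.39 with hotspots of at least 200 bp (Fisher's exact p = 0.122), 1.34 with a 2500 bp window (p = 0.0559) and 1.39 to 1.82 with a library left out.

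Territories with fewer covered bases numbered 121 without scaling, 1098 with quantile normalization, 1138 with scaling inside territories, 1690 with equal-length lists, 1352 with the identifier series as a covariate, 1483 without rescue 6 and null 2, and 1549 to 3533 with a library left out. Territories with more numbered 516 at 10 kb per side and 764 with the series covariate. With that covariate 17 of 92 named genes no longer passed: RAB26, SMARCC2, SS18L1, CLDN1, MAFG, BATF, TEAD2, CCN2, SRXN1, GCLM, NEUROG1, HOXC9, HOXB9, AURKB, ID1, ITGAM and CORO1A. With an estimated correlation 3 lists passed in place of 5.

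Without scaling SMARCA4 (0.00605) and SMARCA2 (0.147) changed sign, and with 10 kb territories NR3C1 (-0.0265), SGK1 (-0.198) and TNFAIP3 (-0.391) did. List directions that turned belonged to lists that did not pass either way, given as adjusted p: no filter, neuronal 0.702 and WNT 0.946; 10 kb, lung and NRF2 0.987, glucocorticoid and WNT 0.808; series covariate, lung 0.978; without rescue 6, null 4 or both rescue 6 and null 2, WNT 0.832, 0.79 and 0.71; without null 3, NRF2 0.982. Over each library left out, WNT ranged from 0.653 to 0.947 and NRF2 from 0.238 to 0.982. In 1822 repeats of named territories 1653 kept direction and side of the threshold, 164 no longer passed and 5 turned; in 399 repeats of lists 373 kept both, 4 no longer passed, 11 newly passed (cell cycle 8, YAP/TEAD 2, hepatic 1) and 11 turned.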

Other observations

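Gene families grouped by symbol stem were examined after the other results were seen, over 209 stems. Collagen genes (COL) rose at 14 and fell at 1 of 37 (camera, adjusted p = 1.3e-05; adjusted p = 0.108 with an estimated correlation), with a median 0.35 above that of all territories. Zinc finger genes (ZNF) rose at 14 and fell at 135 of 394 (adjusted p = 9.9e-05; adjusted p = 0.944 with an estimated correlation). Genes of the stems RGS, regulators of G-protein signalling (9 higher and 1 lower of 17, adjusted p = 0.00363), SERPINB, serine protease inhibitors (4 higher and 0 lower of 11 with limma, adjusted p = 0.0039), and CD (15 higher and 6 lower of 61, adjusted p = 0.0049) stood above other territories. With an estimated correlation none of these 5 stems passed, the smallest of their adjusted p being 0.108.

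Within their own lists gained regions ranked between those in all 10 libraries and other variable regions. In rescue 1 hotspots in gained regions had a median percentile of 60.3 by the authors' score, against 73.0 for regions in all 10 libraries and 33.1 for the other variable regions. In rescue 4 the percentiles were 38.4, 66.9 and 26.3. Regions lost among the other 8 libraries numbered 461, of which 85.7% were found in null 3 and 5.86% in rescue 4.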
